A study of Mus musculus with 16 samples.

How the data were processed

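RNA was measured in 16 sequencing libraries of mouse hepatic progenitor cells, 4 for each combination of genotype (Ptpn1 wild type, WT, or Ptpn1 knockout, KO) and treatment (control or 400 µM palmitic acid for 8 h). Per the labels' protocols, total RNA was depleted of ribosomal RNA, made into libraries with a KAPA RNA HyperPrep kit and sequenced on a HiSeq2000 in paired reads of 76 nucleotides. Cells were grown in DMEM with 10% fetal bovine serum and treated with palmitic acid in DMEM with 5% serum and 1% bovine serum albumin, and the labels do not say which of these media the control libraries had.

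The deposited table holds a signal on a linear scale, normalized counts per its name, for 55421 genes in 16 libraries, with a versioned Ensembl identifier, a symbol and a biotype for each gene. The submitters' processing notes list STAR, RSEM, DESeq2 and limma without their role or version, and the genome build and annotation are not given in the sources used here. Of the 55421 identifiers, 54673 were found with the same version in GENCODE vM21 (GRCm38) and 55240 without regard to version, and coordinates are GRCm38 positions from GENCODE vM21. A further check found 113 symbols with more than 1 entry (230 entries), which were kept apart by identifier.

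Each library's values were whole multiples of 1 step, so reads could be recovered by dividing by it. All values above 0 (100%) came out whole within 0.1 read in every library. The reciprocal of the step equalled the median-of-ratios size factor recomputed from the recovered reads (ratio 1 in every library), so the deposited values are gene reads divided by such factors. The recovered depth was 21553952 to 35693442 gene reads per library. A gene with 0 reads in a group was given a floor of 3 reads over that group for fold changes written as "at least", and a gene with 1 to 3 reads a ratio of means with a 95% interval. These floors and intervals cover counting error only.

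Because the table holds normalized values, limma was used for the main tests, as had been set for that case. Values were tested as log2(value + 1), over the 15239 genes with a value of at least 10 in at least 4 libraries. A linear model of the 4 group means was fitted to all 16 libraries with limma, with a mean-variance trend and robust empirical Bayes, and p-values were adjusted with the Benjamini-Hochberg method within each of 5 comparisons. The comparisons were KO against WT in control, KO against WT after palmitate, palmitate against control in WT, the same in KO, and the difference of the palmitate responses (KO minus WT). A gene was called at an adjusted p under 0.05, two-sided. All fold changes and their standard errors (SE) come from limma on the log2(value + 1) scale, which understates the change of low genes. The level of Ptpn1 was also compared with an exact permutation test.

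Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted with Benjamini-Hochberg over the 26 lists with at least 5 measured members in a comparison. Measured members are those that passed the filter, which a gene high in a single group can pass. Members below it are in no count, so the cell type and histone lists are counted over part of their genes. Their names are the integrated stress response, ER chaperones and ERAD, NRF2 and antioxidant genes, PPAR targets and fatty acid oxidation, fatty acid synthesis and desaturation, cholesterol synthesis, triglyceride synthesis and lipid droplets, NF-kB inflammatory genes, interferon-stimulated genes, the BCL2 family and caspases, p53 targets, autophagy and lysosome, cell cycle and proliferation, progenitor and cholangiocyte markers, hepatocyte markers, mesenchymal and EMT genes, the insulin, IGF and FOXO pathway, ERK targets and growth factor receptors, JAK/STAT signalling, protein tyrosine phosphatases, genes near Ptpn1, macrophage and leukocyte markers, endothelial markers, stellate cell and fibroblast markers, mitochondrially encoded mRNAs, replication-dependent histones and sex-linked genes. Each list was also run with camera at an estimated correlation and with fry, which asks whether a list's genes move on balance one way and does not compare the list with other genes. List medians were recomputed with genes at 0 reads set at their floor, and none of the 108 medians in the 4 comparisons of 2 groups changed.

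Named genes followed a rule. Ptpn1 came first. For each comparison of 2 groups the rule took the 6 largest rises and the 6 largest falls among called genes with a mean of at least 50 in the higher group, no overlap between the 4 libraries of each group and a symbol that is not a predicted or unnamed locus. It added up to 3 called members of each list with the largest absolute change, and for the difference of responses the 5 highest and the 5 lowest called genes. Genes that could not be named were skipped for the next and are not reported here. The excluded prefix Rn was read as Rn followed by a digit, and unnamed loci as 2 capitals followed by at least 4 digits. The comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives chosen after seeing the data were the removal of a GC content and length trend, the other scalings of the list tests, the leave-one-out runs of the Ptpn1 level and of the agreement between genotypes, and that agreement after rescaling to the same total.

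The alternatives were pseudocounts of 0.5 and 5, no filter, a filter at 50, library totals made equal, median-of-ratios factors over the kept genes, quantile normalization, limma array weights, only the compared groups in the fit, the replicate number as a block, a minimum change of 1 on the log2 scale, each library left out in turn, and edgeR quasi-likelihood and DESeq2 Wald tests on the recovered reads. GC content and length were known for 15224 of the 15239 genes (99.9%). The models were tested on simulated data made from the WT control means, raised to at least 10, for all 16 libraries. Genes were changed in KO palmitate alone, so the broad differences between genotypes and the shared palmitate response were absent. Recovery in the real data may therefore differ. For palmitate in KO, 35, 36, 45 and 49 of 50 genes changed 1.25-, 1.5-, 2- and 4-fold were recovered among 15239 genes, with 14 unchanged genes called. For the difference of responses 29, 29, 38 and 47 of 50 were recovered, with 10 unchanged genes called. The list test for that difference called the 1 changed list of 25 genes (1.5-fold) and 0 of 25 unchanged lists.

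Replicate libraries of a group differed by more than sampling noise in all 24 pairs (chi-square per gene of 1.58 to 5.77). Each counted as a separate sample, as labelled, although repeat preparations of 1 culture could differ as much. R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. All deposited library columns were used.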

Results

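Messenger RNA and other long RNA were sequenced from mouse hepatic progenitor cells, also called oval cells, which expand in the injured liver and can form hepatocytes and cholangiocytes. The cells carried Ptpn1 (WT) or lacked it (KO). Ptpn1 encodes the tyrosine phosphatase PTP1B, which acts on the insulin receptor and on JAK kinases. Cells of each genotype were left as controls or were given 400 µM palmitic acid, a saturated fatty acid that stresses liver cells, for 8 h. Each of the 4 groups had 4 libraries, with 21553952 to 35693442 gene reads per library. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical. They also do not say how many cell lines stand for each genotype, so genotype and cell line cannot be told apart. In a principal component analysis the first component held 85.4% of the variance and separated KO from WT libraries, and the second held 3.2% and separated palmitate from control.

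Ptpn1 itself (ENSMUSG00000027540.13, chromosome 2, 167932057 to 167979385, GRCm38) was low in every KO library. In control it stood at 1936.5 ± 39 normalized counts in WT and 329.5 ± 16 in KO (SD, n = 4 each), and the KO level was 17% of the WT level. After palmitate it stood at 1851.9 ± 16.7 in WT and 293.4 ± 11.6 in KO (SD, n = 4 each), or 15.8%. The log2 fold changes of KO against WT were -2.55 ± 0.04 and -2.65 ± 0.04 (SE). Both differences had an exact permutation p of 0.0286, two-sided, the smallest that the 70 assignments of 8 libraries allow. Gene-level values do not show which exons the remaining reads came from.

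**Figure D1:**
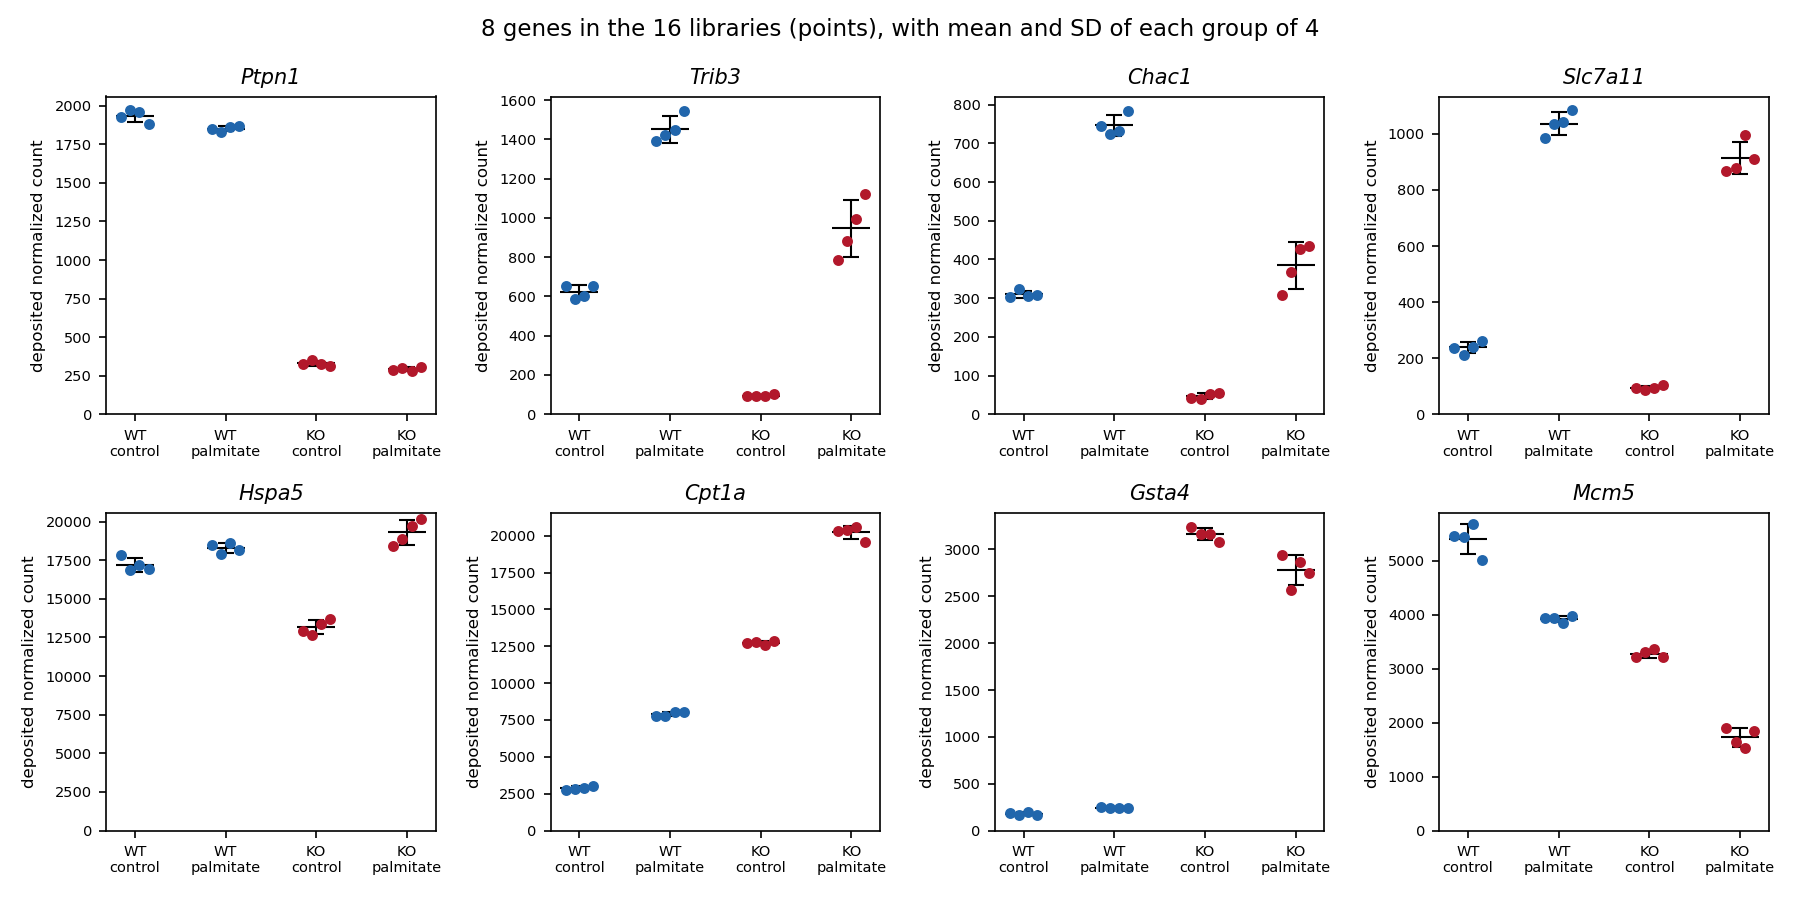
Normalized counts of 8 genes in each of the 16 libraries (vertical axis, 1 panel per gene), with points for libraries, and bars for the group mean and SD of 4 libraries. The KO libraries sit far below the WT libraries for Ptpn1, and Trib3 rises from a lower KO start to 946 against 1450.7 in WT.

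The first comparison asked which transcripts differ between KO and WT cells without added fatty acid. Albumin mRNA (Alb, ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602), the main secreted protein of hepatocytes, stood at 3638.2 ± 235 normalized counts in KO and 1.4 ± 0.874 in WT (SD, n = 4 each). The fibrillar collagen Col3a1 (ENSMUSG00000026043.18, chromosome 1, 45311538 to 45349706) ran the other way, with 350 ± 65 in KO and 35438.8 ± 759 in WT. Of 15239 genes tested with limma, 11744 differed, 5759 higher and 5985 lower in KO, and 3378 of them differed at least 2-fold, 1592 higher and 1786 lower. The split depended on the processing, with 4993 higher and 6798 lower after rescaling to the same total, and 6205 higher and 5657 lower with a GC content and length trend removed. Alb was 10.61 ± 0.33 higher on the log2 scale (SE), Shtn1 9.75 ± 0.34 and Pamr1 9.36 ± 0.46. Thsd4 and the palmitoyltransferase gene Zdhhc15 had no reads in WT control and were at least 2150-fold and at least 948-fold higher in KO. The apolipoprotein gene Apoc1 had 2 reads over the WT control libraries, and its ratio of means was 2230 (95% interval 617 to 18400). Among the largest differences in the other direction, the collagen Col6a5 and Lgi2 had no reads in KO control and were at least 342-fold and at least 129-fold lower. The matrix metalloproteinase Mmp2 had a log2 fold change of -7.69 ± 0.42, Wasf3 of -6.83 ± 0.22, and Lox, which crosslinks collagen, of -6.76 ± 0.29. The metalloproteinase Mmp3 had 1 read over the KO control libraries, and its mean was 633 times higher in WT (95% interval 113 to 25000). These 12 genes did not overlap between the 4 KO and the 4 WT libraries, and their highest adjusted p was 2.76e-10.

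Hepatocyte markers that passed the filter were higher in KO as a list. Members of a list below the filter are left out here and in later counts. Of 17 measured members 15 were higher and 1 lower, over all genes tested and adjusted over the list alone, with a median log2 fold change of 3.06 (camera adjusted p = 3.99e-07). The thyroid hormone carrier Ttr was 7.02 ± 0.09 higher and Apob, the structural protein of very low density lipoproteins, 5.93 ± 0.08. Progenitor and cholangiocyte markers were higher for 17 of 21 members and lower for 4 (median 0.71, camera adjusted p = 0.000476), led by the transcription factor gene Onecut2 at 4.81 ± 0.10. Mesenchymal and EMT genes were lower for 23 of 30 members and higher for 6 (median -1.30, camera adjusted p = 5.18e-06, adjusted p = 0.0995 with an estimated correlation), with Col3a1 at -6.67 ± 0.09. Stellate cell and fibroblast markers, which hold other collagens than that list, were lower for 9 of 11 members and higher for 1 (median -4.43, camera adjusted p = 0.000128, adjusted p = 0.0642 with an estimated correlation). Col6a3 stood at -5.77 ± 0.08, Col6a2 at -5.32 ± 0.05 and the matrix protein gene Postn at -4.63 ± 0.12. All 4 measured sex-linked genes, too few for the list test, were lower in KO (median -1.24), among them the Y-linked genes Ddx3y at -1.39 ± 0.03, Uty at -1.31 ± 0.04 and Eif2s3y at -1.17 ± 0.04. Every count in this paragraph was the same when adjusted over the list alone.

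Genes that burn and store lipids were higher in KO control cells, and genes that make cholesterol were lower. PPAR targets and fatty acid oxidation genes were higher for 18 of 25 members and lower for 4 (median 0.58, camera adjusted p = 0.00018), including the acyl-CoA thioesterase Acot1 at 4.49 ± 0.08, the peroxisomal enzyme Ehhadh at 3.73 ± 0.14 and Ppara, the receptor itself, at 3.61 ± 0.19. Triglyceride synthesis and lipid droplet genes were higher for 18 of 22 and lower for 3 (median 0.66, camera adjusted p = 4e-05), including Cideb at 4.34 ± 0.09 and Dgat2, which makes triglyceride, at 2.76 ± 0.04. Cholesterol synthesis genes were lower for 22 of 25 and higher for 1 (median -0.77, camera adjusted p = 3.67e-07, adjusted p = 0.127 with an estimated correlation). In that list the sterol pathway enzymes Cyp51, Mvd and Msmo1 stood at -1.44 ± 0.03, -1.13 ± 0.04 and -1.09 ± 0.03. NRF2 and antioxidant genes were higher for 18 of 23 and lower for 3 (median 0.47, camera adjusted p = 3.42e-05, adjusted p = 0.263 with an estimated correlation). The glutathione transferase Gsta4 was 4.15 ± 0.05 higher, catalase (Cat) 2.67 ± 0.03 and Gclc, a subunit of the enzyme that starts glutathione synthesis, 2.64 ± 0.03. Autophagy and lysosome genes were higher for 23 of 32 and lower for 4 (median 0.36, camera adjusted p = 9.47e-05, adjusted p = 0.18 with an estimated correlation), with the lysosomal hydrolase gene Hexa at 2.36 ± 0.04 and Npc2, a lysosomal cholesterol carrier, at 0.98 ± 0.03. All these counts were the same adjusted over the list alone.

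Growth and stress genes also separated the genotypes. The insulin, IGF and FOXO pathway was higher for 22 of 27 members and lower for 5 (median 0.55, camera adjusted p = 0.00018, adjusted p = 0.136 with an estimated correlation). The growth factor binding protein genes Igfbp2 and Igfbp6 went opposite ways at 6.95 ± 0.34 and -4.12 ± 0.24, and the growth factor gene Igf2 stood at 4.92 ± 0.29. Cell cycle and proliferation genes were lower in KO for 30 of 34 (31 adjusted over the list alone) and higher for 2 (median -0.46, camera adjusted p = 1.28e-06, adjusted p = 0.107 with an estimated correlation), with the cyclin gene Ccne2 at -1.11 ± 0.07, Rrm2 at -0.88 ± 0.06 and the replication helicase subunit Mcm2 at -0.85 ± 0.04. Integrated stress response genes were lower for 19 of 28 and higher for 5 (median -0.40, camera adjusted p = 0.00164, adjusted p = 0.371 with an estimated correlation). The pseudokinase gene Trib3 stood at -2.71 ± 0.08, Chac1, which degrades glutathione, at -2.70 ± 0.10 and the mitochondrial folate enzyme Mthfd2 at -1.99 ± 0.05. The p53 targets were higher for 11 of 20 and lower for 5 (median 0.33, camera adjusted p = 0.0411, adjusted p = 0.18 with an estimated correlation), with Eda2r at 1.44 ± 0.09, Trp53inp1 at 1.24 ± 0.04 and Sesn1 at -1.16 ± 0.06. That call was also lost after quantile normalization (adjusted p = 0.0522), within a range of 0.0325 to 0.18 over the camera alternatives. Except for the 31 cell cycle genes, adjusting over the list alone left these counts as they were.

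The other 13 tested lists were not called between KO and WT in control, although they held genes that were. ER chaperones and ERAD genes were higher for 8 and lower for 13 of 26 members (camera adjusted p = 0.373), with the chaperone gene Creld2 at -0.90 ± 0.05 and Herpud1 at 0.76 ± 0.04. Fatty acid synthesis genes were higher for 9 and lower for 8 of 17 (adjusted p = 0.482), with the elongase Elovl6 at -2.10 ± 0.03 and the transcription factor gene Mlxipl at 1.93 ± 0.05. NF-kB inflammatory genes were higher for 13 and lower for 8 of 23 (adjusted p = 0.31), with the chemokine gene Ccl7 at 2.51 ± 0.10, and interferon-stimulated genes higher for 5 and lower for 13 of 22 (adjusted p = 0.206), with Gbp2 at -2.74 ± 0.11. The BCL2 family and caspases were higher for 14 and lower for 6 of 23 (adjusted p = 0.138), with the death receptor gene Fas at 2.09 ± 0.06 and Bok at -2.03 ± 0.04. ERK targets and growth factor receptors were higher for 7 and lower for 16 of 28 (adjusted p = 0.181), with Fgfr1 at -2.34 ± 0.05. JAK/STAT genes were higher for 12 and lower for 6 of 21 (adjusted p = 0.182), with a median of 0.22 but a mean of -0.08, and the feedback inhibitor genes Socs1 and Cish stood at -2.95 ± 0.32 and -1.07 ± 0.07. Protein tyrosine phosphatases, a list that holds Ptpn1 itself, were higher for 10 and lower for 9 of 24 (adjusted p = 0.974, median 0.02, mean -0.15). Beside Ptpn1, Ptpn22 stood at -3.02 ± 0.22 and Ptpn13 at 1.53 ± 0.04. Genes near Ptpn1 on chromosome 2 were higher for 10 and lower for 5 of 20 (adjusted p = 0.359), with Snai1 at -4.48 ± 0.24, Nfatc2 at 3.97 ± 0.28 and Tshz2 at 1.80 ± 0.08.

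Markers of other cell types and of RNA composition were measured in the same comparison. Macrophage and leukocyte markers were higher for 3 and lower for 1 of 6 (camera adjusted p = 0.562, median 0.08, mean -0.30), with Cd14 at 1.07 ± 0.04, and endothelial markers higher for 5 and lower for 2 of 9 (adjusted p = 0.359), with Eng at -3.59 ± 0.08 and Esam at 3.40 ± 0.18. Mitochondrially encoded mRNAs, which share reads with nuclear copies and are uncertain, were higher for 5 and lower for 1 of 13 (adjusted p = 0.407). In that list mt-Nd5 stood at 0.39 ± 0.05 with a limma adjusted p of 1.14e-06, which was 0.81 after quantile normalization and 1.74e-12 to 0.81 over the alternatives. Replication-dependent histones were higher for 4 and lower for 0 of 6 (adjusted p = 0.169), with Hist1h2bc at 1.07 ± 0.06 and Hist1h1c at 0.91 ± 0.05. Genes of rRNA biotypes held 0.081% to 0.107% of the counts in the KO libraries and 0.052% to 0.062% in the WT libraries, without overlap. Mitochondrial mRNAs held 3.93% to 4.22% in KO palmitate and 3.391% to 3.798% in the other 3 groups. The rRNA share was also higher after palmitate, without overlap. It was 0.052% to 0.054% in WT control and 0.058% to 0.062% in WT palmitate, and 0.081% to 0.086% and 0.101% to 0.107% in KO. Differences in RNA quality or depletion between the genotypes, or between palmitate and control, are thus not ruled out. The counts of these 13 lists did not change when adjusted over the list alone.

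**Figure D2:**
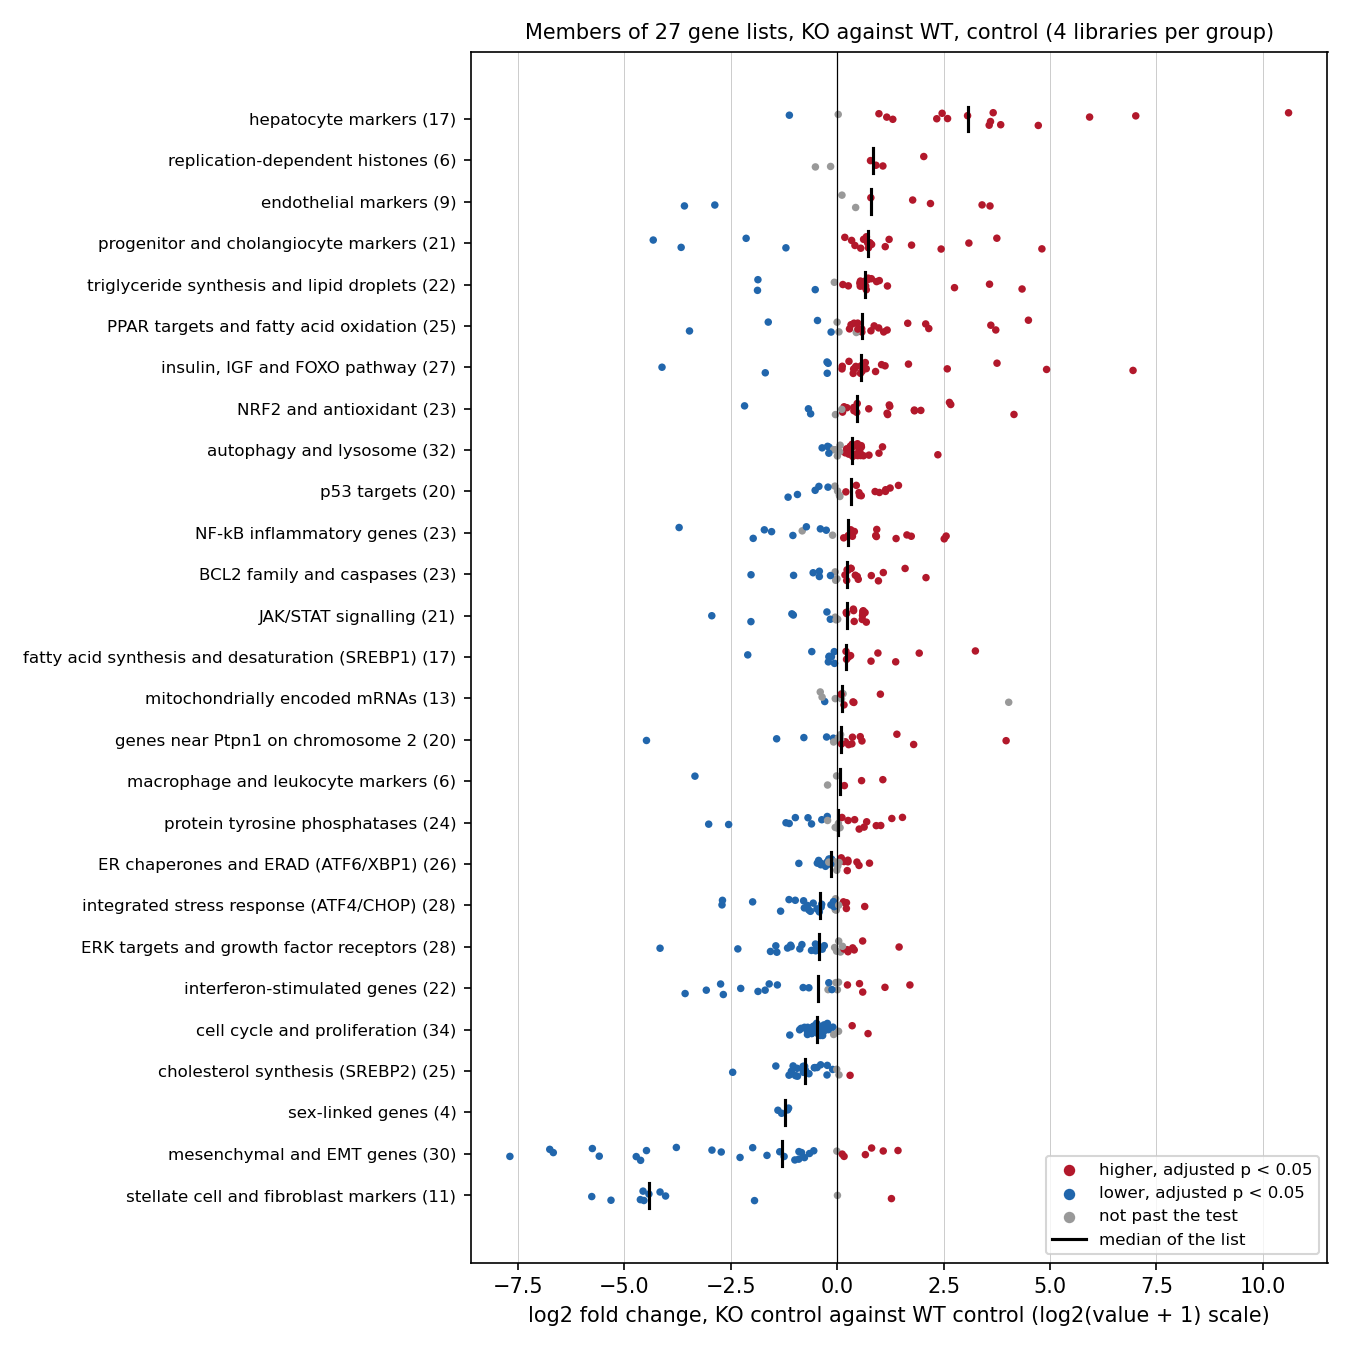
Log2 fold change of KO against WT in control (horizontal axis) for each measured member of the 27 gene lists (1 row per list), red where higher in KO, blue where lower and grey where not called, with a black bar at the list's median. The bar lies at 3.06 for hepatocyte markers and at -4.43 for stellate cell and fibroblast markers.

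KO and WT cells were next compared after palmitate. Alb again stood apart, with 4835.5 ± 116 normalized counts in KO and 0.9 ± 1.02 in WT (SD, n = 4 each), a log2 fold change of 11.52 ± 0.33 (SE). Thsd4 was 9.30 ± 0.33 and Pamr1 9.19 ± 0.46 higher. Prodh2, a hydroxyproline-degrading enzyme, and Zdhhc15 had no reads in WT after palmitate and were at least 1070-fold and at least 928-fold higher in KO. Apoc1 had a ratio of means of 2600 (95% interval 719 to 21500). Col6a5 and Lgi2 had no reads in KO after palmitate and were at least 429-fold and at least 163-fold lower. Mmp2 stood at -7.69 ± 0.42 and Gas1, a growth arrest gene, at -6.90 ± 0.22. The endothelin receptor gene Ednra and Mmp3 had 1 read each over the KO palmitate libraries, and their means were 543 times (95% interval 97.1 to 21500) and 539 times (96.3 to 21300) higher in WT. The highest adjusted p of these 12 genes in limma was 3.4e-10. In all, 11755 of 15239 genes differed, 5811 higher and 5944 lower in KO, and 3392 differed at least 2-fold, 1539 higher and 1853 lower. The split was 4823 higher and 7034 lower after rescaling to the same total, and 6357 higher and 5428 lower with a GC content and length trend removed.

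Between the genotypes after palmitate, 11 lists were called, all in the same direction as in control, where 13 were. The p53 targets (adjusted p = 0.0649) and the integrated stress response were the 2 no longer called. Hepatocyte markers were higher for 15 of 17 members and lower for 1 (median 2.80, camera adjusted p = 5.05e-07), with Ttr at 7.21 ± 0.09. Progenitor and cholangiocyte markers were higher for 16 of 21 and lower for 4 (camera adjusted p = 0.00163), PPAR targets and fatty acid oxidation genes higher for 20 of 25 and lower for 5 (adjusted p = 0.000197), and triglyceride and lipid droplet genes higher for 17 of 22 and lower for 4 (adjusted p = 0.000179). Stellate cell and fibroblast markers were lower for 10 of 11 and higher for 1 (median -4.31, adjusted p = 8.71e-05). These 5 calls held with an estimated correlation. Cholesterol synthesis genes were lower for 21 of 25 and higher for 1 (adjusted p = 1.22e-07, adjusted p = 0.121 with an estimated correlation), with Cyp51 at -1.66 ± 0.03. Cell cycle genes were lower for 32 of 34 and higher for 2 (median -0.62, adjusted p = 9.98e-09, adjusted p = 0.052 with an estimated correlation), with Ccne2 at -1.50 ± 0.07, Mcm2 at -1.24 ± 0.04 and Mcm5 at -1.19 ± 0.05. Mesenchymal genes were lower for 23 of 30 and higher for 6 (adjusted p = 6.04e-06, adjusted p = 0.0878 with an estimated correlation). NRF2 and antioxidant genes were higher for 16 of 23 (17 adjusted over the list alone) and lower for 4 (adjusted p = 0.000197, adjusted p = 0.351 with an estimated correlation). Autophagy and lysosome genes were higher for 24 of 32 and lower for 6, and insulin, IGF and FOXO genes higher for 22 of 27 and lower for 5, both at an adjusted p = 0.00032, with adjusted p = 0.242 and adjusted p = 0.154 with an estimated correlation. Apart from the NRF2 list, counts were the same adjusted over the list alone. Integrated stress response genes were higher for 6 and lower for 17 of 28 (adjusted p = 0.0642), with Chac1 at -0.97 ± 0.10 and Mthfd2 at -1.0 ± 0.05. They were called after rescaling to the same total (adjusted p = 0.0385), after quantile normalization (0.0146), and without KO palmitate library 3 (0.0489) or 4 (0.0365).

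The next comparison asked what palmitate changed in WT cells. Stress response and fat-burning genes rose and cell cycle genes fell, mostly by less than 2-fold. The stress transcription factor gene Atf3 rose by 2.29 ± 0.06 on the log2 scale (SE, n = 4 each), from 326 ± 14.2 to 1591.9 ± 58.4 normalized counts (SD). Slc7a11 (ENSMUSG00000027737.10, chromosome 3, 49892526 to 50443614), the cystine transporter, rose by 2.12 ± 0.07, the colony-stimulating factor gene Csf2 by 2.10 ± 0.15, and Areg, a ligand of the EGF receptor, by 2.01 ± 0.26. Dhrs9, a short-chain dehydrogenase, rose by 1.77 ± 0.15 and Pdk4, which shuts down pyruvate dehydrogenase, by 1.61 ± 0.06. Among the falls were the acute-phase protein gene Saa3 at -1.45 ± 0.15, Tll1 at -1.14 ± 0.29, the smooth muscle actin gene Actg2 at -1.13 ± 0.30, the chemokine gene Ppbp at -1.09 ± 0.08, Plau, the urokinase gene, at -1.02 ± 0.07 and St8sia4 at -1.0 ± 0.13. None of these 12 genes overlapped between the 2 groups, and their highest adjusted p in limma was 0.0032. Of 15239 genes 5734 changed, 2702 up and 3032 down, with a median absolute change of 0.21, and 107 changed at least 2-fold, 86 up and 21 down. With all libraries rescaled to the same total the split was 3656 up and 2265 down (61.7% up against 47.1%). With a GC content and length trend removed it was 2211 up and 3605 down (38% up). The share of rises thus depends on the processing.

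By list, cholesterol synthesis genes rose in WT for 24 of 25 members and fell for 0 (median 0.49, camera adjusted p = 1.39e-28), with Mvd at 0.94 ± 0.04, Lss at 0.89 ± 0.03 and Pmvk at 0.88 ± 0.05. Integrated stress response genes rose for 23 of 28 (26 adjusted over the list alone) and fell for 1 (median 0.39, camera adjusted p = 2.73e-19), including Chac1 at 1.26 ± 0.10. PPAR targets and fatty acid oxidation genes rose for 17 of 25 (18 adjusted over the list alone) and fell for 1 (adjusted p = 8.45e-11), led by Cpt1a, which brings fatty acids into mitochondria, and the lipase inhibitor gene Angptl4, both at 1.46 with SE of 0.03 and 0.07. Fatty acid synthesis genes rose for 14 of 17 and fell for 2 (adjusted p = 9.4e-10), with Acss2 at 1.23 ± 0.08 and Acacb at 1.07 ± 0.13. Triglyceride and lipid droplet genes rose for 12 of 22 and fell for 2 (adjusted p = 0.000177), with the phosphatidate phosphatase Lpin1 at 1.01 ± 0.05, Cideb at 0.93 ± 0.09 and the lipase Lipe at 0.71 ± 0.07. Cell cycle genes fell for 24 of 34 (25 adjusted over the list alone) and rose for 0 (median -0.20, adjusted p = 1.37e-12), with the cyclins Ccnd1 at -0.84 ± 0.06, Ccne2 at -0.71 ± 0.07 and Ccne1 at -0.65 ± 0.09. These 6 calls held with an estimated correlation. The labels do not give the medium of the control cells, so a difference in serum and albumin between treated and control cells is not excluded in either genotype.

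In WT, 5 more lists were called with the preset correlation alone. NRF2 and antioxidant genes rose for 14 of 23 and fell for 2 (adjusted p = 2.55e-05, adjusted p = 0.281 with an estimated correlation), including the heme oxygenase gene Hmox1 at 0.99 ± 0.07, Srxn1 at 0.53 ± 0.04 and Gsta4 at 0.45 ± 0.05. Autophagy and lysosome genes rose for 20 of 32 (21 adjusted over the list alone) and fell for 3 (4 in the list alone; adjusted p = 5.7e-05, adjusted p = 0.216 with an estimated correlation), with the autophagy receptor Sqstm1 at 0.72 ± 0.03 and Bnip3 at 0.44 ± 0.04. ER chaperones and ERAD genes rose for 10 of 26 (11 adjusted over the list alone) and fell for 3 (adjusted p = 0.00838, adjusted p = 0.319 with an estimated correlation), with Herpud1 at 0.74 ± 0.04 and the transcription factor gene Xbp1 at 0.32 ± 0.04. Interferon-stimulated genes rose for 11 of 22 and fell for 1 (2 adjusted over the list alone; adjusted p = 0.00507, adjusted p = 0.216 with an estimated correlation), with Irf7 at 0.97 ± 0.21. Mesenchymal genes fell for 13 of 30 (14 adjusted over the list alone) and rose for 4 (adjusted p = 0.00507, adjusted p = 0.281 with an estimated correlation), with the growth factor-like Ccn2 at -0.93 ± 0.15 and the contractile genes Tagln at -0.91 ± 0.15 and Acta2 at -0.78 ± 0.14. That mesenchymal call was also lost after quantile normalization (adjusted p = 0.0509, and 0.00182 to 0.281 over the camera alternatives). Outside the called lists, the immediate-early genes Egr1 and Fos rose by 1.32 ± 0.12 and 1.02 ± 0.20, the death genes Bmf and Bok moved by 0.66 ± 0.06 and -0.61 ± 0.04, and 0 of the 11 stellate cell and fibroblast markers passed the limma test, adjusted or over the list alone.

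In KO cells palmitate raised stress response genes and lowered cell cycle genes. Trib3 (ENSMUSG00000032715.9, chromosome 2, 152337422 to 152344032) rose by 3.30 ± 0.08 on the log2 scale (SE, n = 4 each), from 94.6 ± 4.29 to 946 ± 147 normalized counts (SD). Slc7a11 rose by 3.27 ± 0.07, Chac1 by 2.99 ± 0.10, Atf3 by 2.71 ± 0.06, Areg by 2.66 ± 0.26 and Csf2 by 2.54 ± 0.15. The peptide hormone gene Apln fell by 1.58 on the log2 scale, the replication licensing factor Cdc6 by 1.21, Ppbp by 1.16, Ccne2 by 1.09, the uracil-DNA glycosylase Ung by 1.06 and Slfn9 by 1.05, with SE of 0.06 to 0.15. None of these 12 genes overlapped between the groups, and their highest adjusted p in limma was 7.88e-09. Of 15239 genes 5960 changed, 2845 up and 3115 down, with a median absolute change of 0.22, and 159 changed at least 2-fold, 108 up and 51 down. With all libraries rescaled to the same total the split was 3274 up and 2726 down (54.6% up against 47.7%). The majority direction thus depends on the scaling. With a GC content and length trend removed it was 2639 up and 3477 down (43.1% up). KO palmitate library 1 stood apart from its group, with a chi-square per gene of 5.18 to 5.77 against the other 3 libraries, which had 2.24 to 2.9 among themselves. Without it 6248 genes changed.

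By list, integrated stress response genes rose in KO for 24 of 28 members and fell for 1 (median 0.55, camera adjusted p = 5.64e-25), and ER chaperones and ERAD genes rose for 25 of 26 and fell for 0 (median 0.28, camera adjusted p = 4.04e-15). Among the latter were Herpud1 at 0.61 ± 0.04, Hspa5, the main ER chaperone, at 0.55 ± 0.03 and Xbp1 at 0.51 ± 0.04. Cholesterol synthesis genes rose for 24 of 25 and fell for 1 (median 0.42, adjusted p = 5.64e-25), with the sterol sensor gene Insig1 at 0.99 ± 0.03, Pmvk at 0.87 ± 0.05 and Lss at 0.86 ± 0.03. PPAR targets and fatty acid oxidation genes rose for 15 of 25 (16 adjusted over the list alone) and fell for 1 (adjusted p = 2.01e-10), with Angptl4 at 1.99 ± 0.07 and Pdk4 at 1.10 ± 0.06. Fatty acid synthesis genes rose for 12 of 17 and fell for 2 (adjusted p = 2.85e-08), with Acacb at 1.07 ± 0.13 and Acss2 at 0.98 ± 0.08. Cell cycle genes fell for 32 of 34 (33 adjusted over the list alone) and rose for 0 (median -0.35, adjusted p = 8.09e-24), with Ccne1 at -1.02 ± 0.09 and Mcm3 at -0.93 ± 0.05. These 6 calls held with an estimated correlation.

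Triglyceride and lipid droplet genes rose in KO for 11 of 22 (13 adjusted over the list alone) and fell for 3 (6 in the list alone; adjusted p = 0.0269, adjusted p = 0.111 with an estimated correlation), with Lpin1 at 0.81 ± 0.05 and Lipe at 0.54 ± 0.07. Interferon-stimulated genes rose for 8 of 22 and fell for 2 (adjusted p = 0.0421, adjusted p = 0.373 with an estimated correlation), with Gbp2 at 0.51 ± 0.11. That call was lost after rescaling to the same total (adjusted p = 0.0557), after quantile normalization (0.0758), and without KO control library 2 (0.078) or KO palmitate library 4 (0.0617), within a range of 0.0209 to 0.373 over the camera alternatives. Autophagy and lysosome genes rose for 14 of 32 and fell for 5 (adjusted p = 0.0441, adjusted p = 0.619 with an estimated correlation), with Bnip3 at 0.37 ± 0.04 and Sqstm1 at 0.34 ± 0.03. That call was lost after removal of a GC content and length trend (adjusted p = 0.0651) and without KO control library 4 (0.0942) or KO palmitate library 1 (0.269), within a range of 0.00385 to 0.619 over the camera alternatives. NRF2 and antioxidant genes rose for 6 and fell for 7 of 23 and were not called (adjusted p = 0.996), with Hmox1 at 0.66 ± 0.07, Srxn1 at 0.44 ± 0.04 and the NADPH-producing enzyme G6pdx at -0.24 ± 0.04. Nos2, the inducible nitric oxide synthase gene, rose by 1.26 ± 0.07 and the immediate-early genes Egr1 and Fos by 1.91 ± 0.12 and 1.47 ± 0.20, in lists that were not called.

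**Figure D3:**
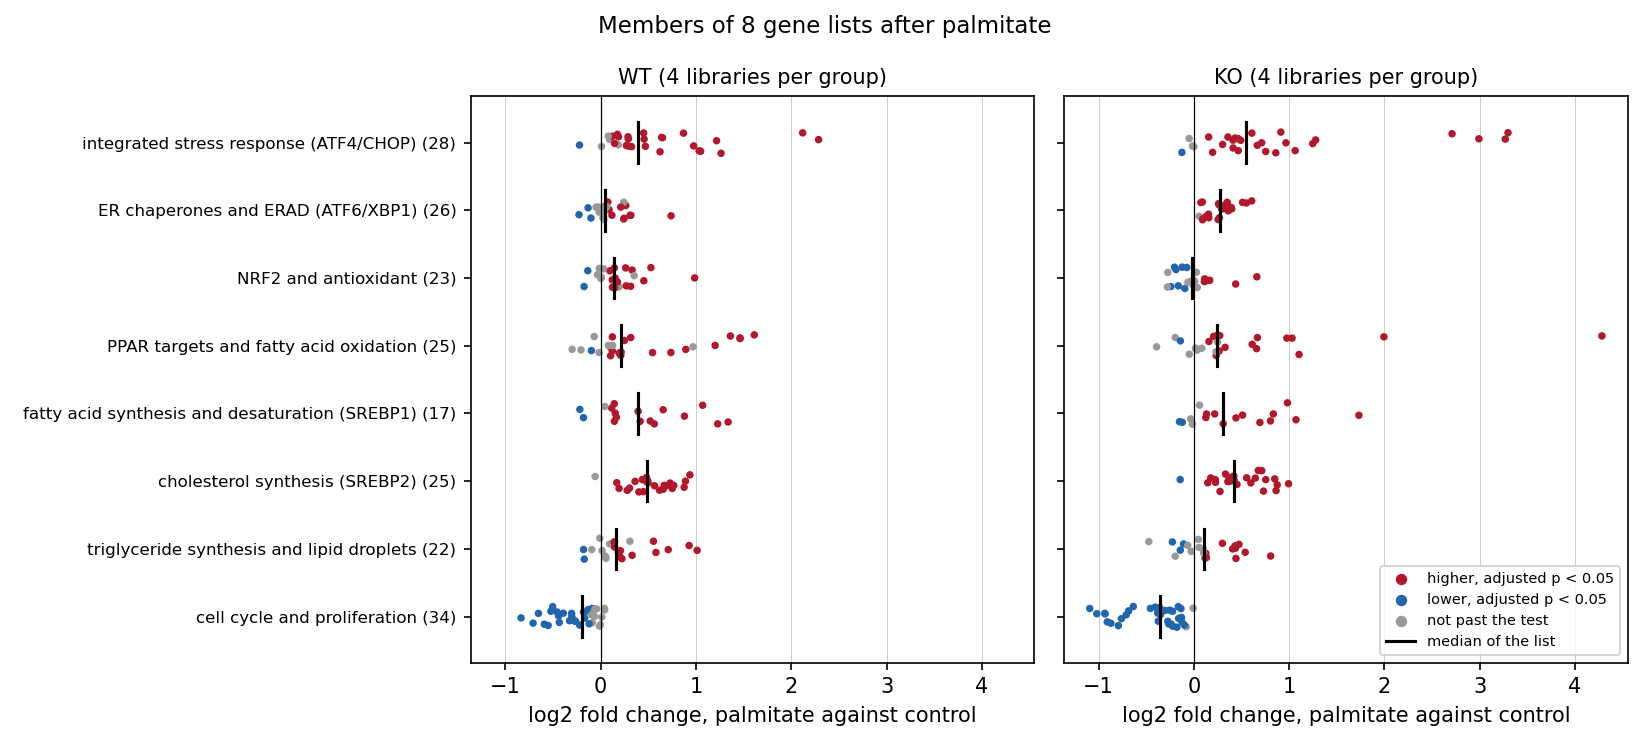
Log2 fold change of palmitate against control (horizontal axis) for each measured member of 8 gene lists, with WT and KO in separate panels, red where risen, blue where fallen and grey where not called, and a black bar at the list's median. The bar of the integrated stress response lies at 0.39 in WT and 0.55 in KO, and that of the cell cycle list at -0.20 and -0.35.

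The palmitate responses of the genotypes were then set side by side across genes, which are not independent replicates. Of 3719 genes called in both, 1564 rose in both and 2000 fell in both, against 504.4 and 619.8 if the lists of calls were independent, and 155 went opposite ways. The log2 fold changes of all 15239 genes had a Pearson r of 0.457 (jackknife SE 0.043 over libraries) and a Spearman rho of 0.522. The 2 responses share no libraries. The genotype difference in control and that after palmitate had an r of 0.973, also over separate libraries, and 99.4% of the 10610 genes called in both had the same sign.

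The last comparison asked which genes responded differently to palmitate in KO and WT, as KO response minus WT response. Higher and lower responses refer to the signed log2 change, so for genes that fall a lower response is a deeper fall. The stress genes Trib3 and Chac1 responded more in KO, by 2.08 ± 0.11 and 1.73 ± 0.14 on the log2 scale (SE, 4 libraries in each of 4 groups), and both started lower there. Trib3 stood at 624 ± 36.3 and 1450.7 ± 67.1 normalized counts in WT control and palmitate, and at 94.6 ± 4.29 and 946 ± 147 in KO (SD). Creb3l3, a liver transcription factor gene, had a difference of 2.11 ± 0.35, the peptide gene Adm2 of 2.22 ± 0.60 and the immediate-early gene Egr2 of 1.59 ± 0.43. The lowest differences were those of the glutathione transferase Gsta1 at -1.68 ± 0.42, the aquaglyceroporin Aqp9 at -1.64 ± 0.22, Ednra at -1.55 ± 0.37, the formin gene Fmnl1 at -1.44 ± 0.20 and Tex15 at -1.32 ± 0.41. The highest adjusted p of these 10 genes in limma was 0.0393, that of Tex15. In all, 1508 of 15239 genes differed, 638 with a higher and 870 with a lower response in KO, and 56 by at least 2-fold, 23 higher and 33 lower. After rescaling to the same total the split was 489 higher and 1141 lower (30% higher against 42.3%). With a GC content and length trend removed it was 712 and 728 (49.4% higher). Without KO palmitate library 1, which stood apart from its group, 1784 genes differed.

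Of those 10 genes, 3 rested on the setting. Adm2 (adjusted p = 0.0271) was lost with a pseudocount of 0.5 (0.0735) and without KO control library 2 (0.0613), KO palmitate library 3 (0.062) or KO palmitate library 4 (0.0524), within a range of 0.000271 to 0.0735. Ednra (0.00599), with 1 read in all KO palmitate libraries, was lost with a pseudocount of 5 (0.122) and with DESeq2 (0.0565), within a range of 0.000983 to 0.122. Tex15 was lost with edgeR (0.215), DESeq2 (0.26), no filter (0.0602), a filter at 50 (0.0518) and quantile normalization (0.102), within a range of 0.00725 to 0.26. It was also lost without any 1 of KO control libraries 1 to 4 (0.0669, 0.0699, 0.0689 and 0.0659), KO palmitate libraries 2 to 4 (0.0644, 0.0611 and 0.0862), WT control libraries 2 and 3 (0.0779 and 0.0798) or WT palmitate libraries 2 to 4 (0.0755, 0.0563 and 0.0584).

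ER chaperones and ERAD genes had a higher response in KO for 13 of 26 members (18 adjusted over the list alone) and a lower one for 0 (1 in the list alone; median 0.13, camera adjusted p = 5.43e-13), with Hspa5 at 0.46 ± 0.04, Sdf2l1 at 0.41 ± 0.10 and Dnajc3 at 0.33 ± 0.07. Cell cycle genes had a lower response in KO for 15 of 34 (22 adjusted over the list alone) and a higher one for 0 (median -0.14, camera adjusted p = 5.23e-13), with the replication helicase subunits Mcm5 at -0.47 ± 0.07 and Mcm2 at -0.39 ± 0.06 and the cyclin Ccne2 at -0.38 ± 0.11. That list thus fell further after palmitate in KO, with a median of -0.35 against -0.2 in WT. These 2 calls held with an estimated correlation. Integrated stress response genes had a higher response in KO for 13 of 28 (17 adjusted over the list alone) and a lower one for 3 (median 0.16, camera adjusted p = 4.46e-09, adjusted p = 0.18 with an estimated correlation), with Slc7a11 at 1.15 ± 0.10 beside Trib3 and Chac1. NRF2 and antioxidant genes had a lower response in KO for 10 of 23 (13 adjusted over the list alone) and a higher one for 0 (median -0.13, camera adjusted p = 1.62e-08, adjusted p = 0.199 with an estimated correlation), with Gsta4 at -0.64 ± 0.07, G6pdx at -0.42 ± 0.05 and Gclc at -0.30 ± 0.04.

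The other 5 list calls also went with the preset correlation alone. NF-kB inflammatory genes had a higher response in KO for 5 of 23 and a lower one for 8 (13 adjusted over the list alone; adjusted p = 0.00678, adjusted p = 0.22 with an estimated correlation), with the chemokine Ccl20 at -1.04 ± 0.10 but Nos2 at 0.83 ± 0.10 and Cxcl10 at 0.67 ± 0.10. Autophagy and lysosome genes had a lower response for 4 of 32 (6 adjusted over the list alone) and a higher one for 0 (1 in the list alone; adjusted p = 0.0087, adjusted p = 0.404 with an estimated correlation), with Sqstm1 at -0.38 ± 0.04 and Hexa at -0.37 ± 0.06. The BCL2 family and caspases had a lower response for 4 of 23 and a higher one for 0, also adjusted over the list alone (adjusted p = 0.0178, adjusted p = 0.121 with an estimated correlation), with the death gene Pmaip1 at -0.35 ± 0.05 and the survival gene Bcl2l1 at -0.26 ± 0.05. Replication-dependent histones had a higher response for 2 of 6 (3 adjusted over the list alone) and a lower one for 0 (adjusted p = 0.0146, adjusted p = 0.199 with an estimated correlation), Hist1h2bc at 0.46 ± 0.08 and Hist1h1c at 0.34 ± 0.07. Mitochondrially encoded mRNAs were called upward with 1 higher and 0 lower of 13, also adjusted over the list alone (adjusted p = 0.00584, adjusted p = 0.332 with an estimated correlation), although their median of 0.15 and mean of -0.02 differ in sign. That call and that of mt-Co1, at 0.15 ± 0.04, were lost after quantile normalization (adjusted p = 0.0877 and 0.607, within ranges of 0.000737 to 0.332 and 0.00222 to 0.607).

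None of the 4 lipid lists was called for the difference of responses, while some members were. PPAR targets and fatty acid oxidation genes had a higher response in KO for 2 and a lower one for 5 of 25 (5 and 6 adjusted over the list alone; adjusted p = 0.318, median -0.06, mean 0.06). However, fry gave them an adjusted p of 0.00271 downward. Triglyceride and lipid droplet genes had a higher response for 1 and a lower one for 5 of 22 (1 and 7 adjusted over the list alone; adjusted p = 0.118), with an adjusted p of 0.00842 downward in fry. Fatty acid synthesis genes had a higher one for 2 and a lower one for 3 of 17, also adjusted over the list alone (adjusted p = 0.896). Among the PPAR targets Cpt1a went from 2867.1 ± 129 to 7899 ± 153 normalized counts in WT and from 12740.2 ± 140 to 20226.3 ± 433 in KO (SD), a difference of -0.80 ± 0.04 (SE), and Angptl4 had one of 0.53 ± 0.09. Cholesterol synthesis genes had a higher response for 3 and a lower one for 4 of 25, also adjusted over the list alone (adjusted p = 0.351), but the list was called after quantile normalization (adjusted p = 0.00448). ERK targets and growth factor receptors had a higher response for 1 and a lower one for 6 of 28 (2 and 8 adjusted over the list alone; adjusted p = 0.129), among them the ERK phosphatase genes Dusp4 at -0.61 ± 0.07 and Dusp6 at -0.39 ± 0.05. That list was called without WT control library 2 (adjusted p = 0.0498).

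**Figure D4:**
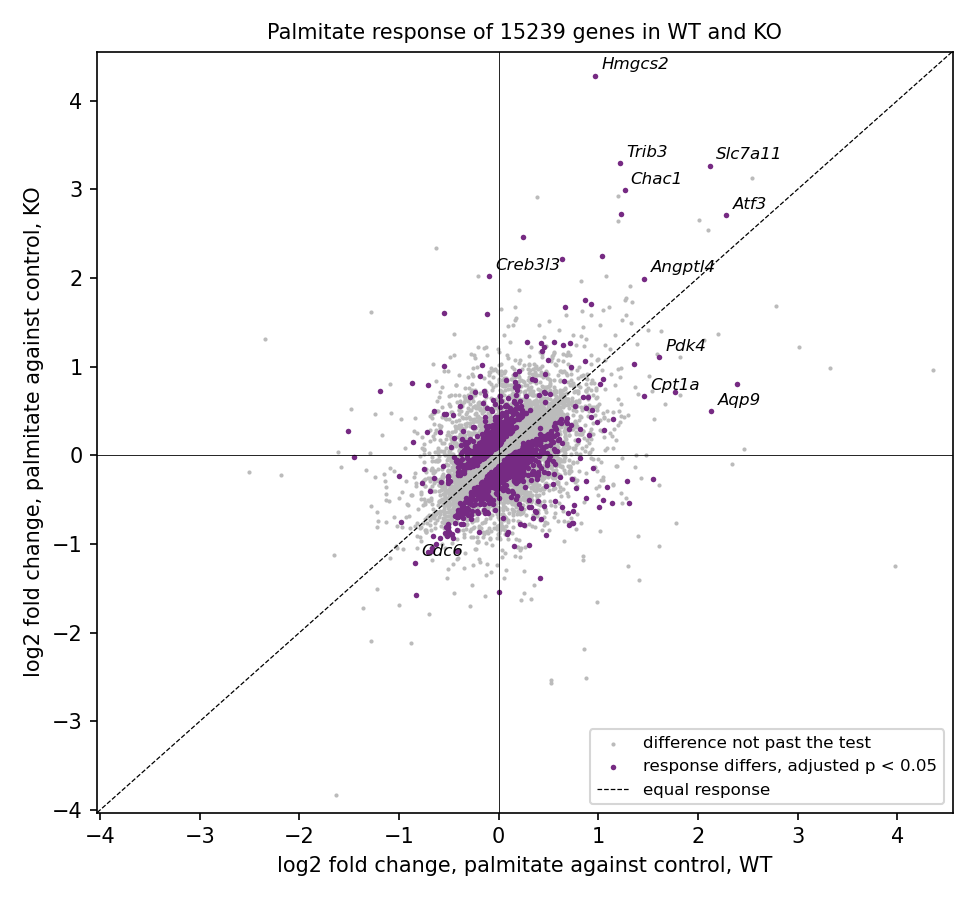
Log2 fold change of palmitate against control in WT (horizontal axis) and in KO (vertical axis) for 15239 genes, grey, with the 1508 genes whose response differed in purple and a dashed line where the responses are equal. Trib3, Chac1 and Slc7a11 lie above the line, and Cpt1a and Aqp9 below it.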

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

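The tests of diluted or mixed cell types, of DNA kept around Ptpn1 and of a common end level were chosen after the results were seen. Those of scaling and of GC content and length were added after the data were examined, before their own values were known.

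Other groupings of the same libraries were tested for each count of genes. Of the 35 splits of the 8 libraries, 1 gave as many calls in each comparison of 2 groups, the real one, the smallest share that 35 splits allow. Every other split mixes the groups, so a group effect widens the spread there and lowers the calls. The splits treat these libraries as separate samples and do not exclude chance between cultures or cell lines. The real counts were 11744 and 11755 for KO against WT in control and after palmitate, where the highest other split gave 1 and 0 calls. They were 5734 and 5960 for palmitate in WT and KO, where the highest other split gave 5 and 937. For the difference of responses, 1 of 100 relabellings of treatment within genotypes, the real one, gave 1508 calls or more, and the highest other gave 904. Relabelling also breaks up the palmitate response that both genotypes share, which widens the spread. It therefore cannot decide whether the responses differ between genotypes.

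The breadth of the difference between KO and WT cells was the first pattern weighed. Another cell type diluting KO-like cells in the WT cultures would lower keratins as much as hepatocyte markers, but the medians over KO against WT were 0.48 for 4 keratins (Krt7, Krt8, Krt18 and Krt19) and 3.06 for the hepatocyte list, a gap of 2.58, which argues against it unless the other cells carry these keratins. Fibroblasts or stellate cells mixed into WT would bring their other abundant transcripts. Col1a1 stood at 62300 normalized counts in WT control beside 93.9 for Dcn, 4.53 for Lum and 0 for Thy1. The lowest of these 3 ratios was 663, that of Dcn, which goes against such cells so far as they carry these genes. Other markers in the list, such as Lrat and Des, were not looked at in this test. However, Col3a1 (35400), Col6a1 (21400) and Postn (4890) were abundant in WT control, and Dcn was lower in KO control (3.12). The genes thus do not all go the same way. DNA of another strain kept around Ptpn1 could directly account for little, since 2.87% of the calls of at least 2-fold lay within 20 Mb of it. However, 97 of 339 genes there (28.6%) differed at least 2-fold against 22% elsewhere (Fisher's exact test, p = 0.00536, two-sided). That test takes neighbouring genes as independent, and other regions of the same size were not ranked beside this one. It therefore cannot tell whether the region is unusual. Effects of genes near Ptpn1 on genes elsewhere were not tested, and the share of 2.87% does not speak to them. The genotype and a difference between cell lines, cultures or RNA preparation remain open, since the labels tie each genotype to its own cells.

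The second pattern weighed was the stronger response of the integrated stress response and ER chaperone lists in KO. With a GC content and length trend removed the larger adjusted camera p of the 2 lists was 1.52e-10, so these trends as a whole do not account for it, while rescaling to the same total (7.32e-09) decides nothing, since it moves nearly all genes of a library alike. A lower start in KO with a common end level stays open. Of the 26 members with a larger rise in KO, 20 were lower in KO control. Choosing members by a larger rise itself favours a lower start or a higher end in KO, so that count partly restates the choice. Over these members the median absolute log2 difference between KO and WT was 0.26 in control and 0.19 after palmitate (73% left), where that over all genes after palmitate was 0.4. After palmitate 11 of the 26 were lower and 12 higher in KO, so the end levels did not settle it, and for the integrated stress response list the call was lost with an estimated correlation (adjusted p = 0.18). A stronger stress response to palmitate in cells without Ptpn1 is a hypothesis that stays open beside a difference between cell lines.

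Other results came up because the difference of the palmitate responses passed its own test, in 1508 genes and in 9 lists. Beside the integrated stress response (camera adjusted p = 4.46e-09) and ER chaperones (5.43e-13) these were NRF2 and antioxidant genes (1.62e-08), NF-kB genes (0.00678), the BCL2 family and caspases (0.0178), autophagy and lysosome (0.0087), the cell cycle (5.23e-13), mitochondrially encoded mRNAs (0.00584) and replication-dependent histones (0.0146). With an estimated correlation only ER chaperones and the cell cycle were still called, and the other 7 had adjusted p of 0.121 to 0.404. As KO minus WT on the log2 scale, positive differences were those of Adm2 (2.22), Creb3l3 (2.11), Trib3 (2.08), Chac1 (1.73), Egr2 (1.59), Slc7a11 (1.15), Nos2 (0.83), Cxcl10 (0.67), Angptl4 (0.53), Hspa5 (0.46), Hist1h2bc (0.46), Sdf2l1 (0.41), Hist1h1c (0.34), Dnajc3 (0.33) and mt-Co1 (0.15). Negative differences were those of Gsta1 (-1.68), Aqp9 (-1.64), Ednra (-1.55), Fmnl1 (-1.44), Tex15 (-1.32), Ccl20 (-1.04), Cpt1a (-0.80), Gsta4 (-0.64), Dusp4 (-0.61), Mcm5 (-0.47), G6pdx (-0.42), Mcm2 (-0.39), Dusp6 (-0.39), Sqstm1 (-0.38), Ccne2 (-0.38), Hexa (-0.37), Pmaip1 (-0.35), Gclc (-0.30) and Bcl2l1 (-0.26).

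Single libraries stood far from the other 3 of their group by Dixon's ratio in 37 of 628 groups tested (5.9%; 151 genes and 6 library measures), and chance gives about 1 in 20. WT control library 4 held 6 of these and KO palmitate library 1 held 5. The ratio takes no account of level, and some flags lie near the floor. Those of 1.0 each rest on a single read, with 0 in the rest of the group. They are Mmp3 at 1.31 normalized counts in KO control and 1.11 in KO palmitate, and Ednra at 0.93. Alb (2.73), Shtn1 (3.23) and Aqp9 (4.31) in WT control and Actg2 (1.9) in KO control were also low. Among library measures, the share of reads in the 10 highest genes was 7.28% in KO control library 3 (ratio 0.889). In WT control, the ratios were 0.916 for Shtn1, 0.902 for Egr1, 0.854 for Aqp9, 0.853 for Pmaip1, 0.847 for Ccnd1 and 0.84 for Gsta1 in library 4, 0.878 for Alb and 0.831 for Csf2 in library 2, and 0.853 for Insig1 in library 1. In WT palmitate, they were 0.946 for Acta2 and 0.84 for Gsta4 in library 1, 0.876 for Cat and 0.852 for Areg in library 2, and 0.85 for Ddx3y in library 3. In KO control, they were 1.0 for Mmp3 and 0.905 for Col6a2 in library 1, 0.911 for Irf7, 0.881 for Acot1 and 0.864 for Dnajc3 in library 2, 0.972 for Ccne2 and 0.845 for Srxn1 in library 3, and 0.946 for Ccl7, 0.899 for Csf2 and 0.843 for Actg2 in library 4. In KO palmitate, they were 0.931 for Lss, 0.866 for Ddx3y, 0.86 for Dusp4, 0.849 for Ccl7 and 0.845 for Bnip3 in library 1, 0.91 for Eng and 0.83 for Dusp6 in library 2, 1.0 for Mmp3, 0.837 for Gas1 and 0.834 for Ppara in library 3, and 1.0 for Ednra and 0.888 for Msmo1 in library 4.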

How the results depend on the processing

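No named gene, list test or correlation called in both runs changed direction under any alternative that was run on it. List tests were not run with other pseudocounts, other filters, array weights, only the compared groups, edgeR or DESeq2. The protein tyrosine phosphatases, not called upward by camera for KO against WT (adjusted p = 0.974 in control and 0.999 after palmitate), were called downward by fry (0.000749 and 0.00108). That list holds Ptpn1 itself, and it was not run without it. Among all genes, some called in both runs had opposite directions: 16 and 54 for KO against WT in control and after palmitate with a GC content and length trend removed, and 6 and 15 there, and 1 each for palmitate in WT and KO, with quantile normalization. The majority direction of calls turned for palmitate in WT and KO after rescaling to the same total and for both comparisons of genotypes with the GC content and length trend removed. For KO against WT after palmitate it also turned with a filter at 50 (5156 higher, 5120 lower). The alternatives chosen after seeing the data are named with the methods. Of 417 results for named genes, 377 kept their direction and call in every alternative run on them, 39 lost the call in some, and 1 gained it, that of Ptpn1 for palmitate in WT with the GC content and length trend removed (adjusted p = 0.0128). A filter at 50 gave no value for 40 of them. The minimum change was applied to counts of genes only, and 188 of the 414 called named results lie below it. With a minimum change of 1 on the log2 scale, 3378, 3392, 107, 159 and 56 genes were left of 11744, 11755, 5734, 5960 and 1508, since most changes were smaller. Leaving out each library in turn gave 11470 to 11567, 11443 to 11618, 5004 to 5771, 5245 to 6248 and 1187 to 1784 genes, with fewer samples in the fit. With edgeR the counts were 11758, 11891, 6231, 5943 and 1602, and with DESeq2 11476, 11595, 5731, 5534 and 1546. The fit of only the compared groups gives no value for the difference of responses. The correlation of the palmitate responses was 0.457, and 0.635 over genes called in either genotype, since genes called in neither were left out. Lists not called gained a camera call in some runs: replication-dependent histones for KO against WT after palmitate when rescaled to the same total (0.0262) and with quantile normalization (0.0317), and for palmitate in KO without KO control library 1 (0.0438), mesenchymal genes for the difference of responses without KO control library 3 (0.0292), NF-kB genes for palmitate in WT with the GC content and length trend removed (0.0399), and mitochondrial mRNAs for palmitate in KO with that trend removed (0.0165) and without KO control library 3 (0.0323) or KO palmitate library 3 (0.0397) or 4 (0.0458). Of the list tests 53 were called, 23 with an estimated correlation and 100 with fry, which asks another question. Counting error limits the genes with few reads in a group, whose fold changes are bounds or wide intervals.

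The replicate numbers did not pair the libraries: same-number libraries had correlations of -0.111 to 0.061 over 24 pairs, and 2 of 16 libraries correlated best with their own number. With the replicate block the counts were 11805, 11836, 5942, 6186 and 1820, and 53 list tests were called.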

Other observations

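The test of chance spread between chromosomes was chosen after the chromosome medians were seen, the genes described first were chosen after their values were seen, and the other 2 chromosome tests were written before their results.

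A few genes known to be imprinted, expressed from 1 parental copy, are given as single values in KO and WT control cells. They stand for no group, since 77.1% of all tested genes differed in this comparison and imprinted genes were not tested as a list. The noncoding RNA H19 (chromosome 7, 142575529 to 142578143, GRCm38) stood at 112 ± 12.8 normalized counts in WT and 1.83 ± 1.54 in KO (SD, n = 4 each), a log2 fold change of -5.52 ± 0.45 (SE), while its neighbour Igf2 (142650766 to 142666816) went from 1.67 ± 0.815 in WT to 77.2 ± 6.41 in KO. Peg10 was lower in KO, with a log2 fold change of -4.01 ± 0.18, and so was Snrpn, with one of -3.04 ± 0.12. Plagl1, a zinc finger gene that arrests growth, was 4.77 ± 0.18 higher, Peg3 1.20 ± 0.05, and the noncoding RNAs Kcnq1ot1 and Airn 1.11 ± 0.14 and 1.12 ± 0.13.

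Other single genes, picked in the same way, were these. The adhesion gene Cdh1 was 3.09 ± 0.04 higher in KO control, the hepatocyte regulator Hnf4a 2.46 ± 0.03, and the keratins Krt8, Krt18, Krt19 and Krt7 0.62 ± 0.02, 0.55 ± 0.03, 0.42 ± 0.04 and 0.34 ± 0.03. Epcam, an oval cell surface marker, had 0 reads in the WT libraries and 1.77 ± 1.22 normalized counts in KO control. The p53 targets Cdkn1a and Mdm2 were 0.89 ± 0.03 and 0.99 ± 0.02 higher in KO, and the cell cycle inhibitor gene Cdkn2a stood at -1.26 ± 0.05.

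Median differences between KO and WT varied by chromosome. Over 10421 autosomal protein-coding genes with a mean of at least 100, the median log2 fold change in control was -0.30 on chromosomes 4 and 14 and -0.23 on chromosome 15, against 0.20 on chromosome 9 and 0.19 on chromosome 13, and after palmitate these medians were -0.27, -0.28, -0.22, 0.21 and 0.20. Chance spread was tested with 10000 random gene sets per chromosome, and 11 of 19 autosomes lay outside all of them. The random sets draw genes singly and do not allow for neighbouring genes that vary together. That count thus shows that genes of a chromosome did not move independently, and not why. A few gene clusters would leave most of a chromosome level, but 20 of 20 windows of 20 Mb on the 3 lowest autosomes had a median below 0 (100%), against 40 of 111 on the other autosomes (36%). These 3 were picked by their medians in the same data, which favours windows below 0 there. Without genes that differ at least 2-fold they kept 84.5% to 91% of their shift. Leaving out genes at both ends moves a median little, so that share decides little. Windows going 1 way were not confined to these 3 autosomes. All windows had a median below 0 on chromosome 11 and above 0 on chromosomes 2, 7, 9, 13, 18 and 19. On chromosome 13 the window medians ran from 0.20 to 0.37 over the first 4 and stood at 0.03 in the last 2. The chromosome medians were not recomputed with a GC content and length trend removed, which turned the majority direction of calls in this comparison. A candidate explanation for chromosomes 4, 14 and 15 is a difference in chromosome copies between the cultured lines, which gene-level values cannot test.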
